A study of Mus musculus with 16 samples.

How the data were processed

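Per the labels, the series holds 16 libraries of mouse E14 embryonic stem cells grown with serum, leukaemia inhibitory factor, CHIR99021 and PD0325901. They form 8 groups of 2 libraries from 3 sequencing projects. Newly synthesized RNA, labelled with the uridine analogue 4-thiouridine (4sU) for 15 min and pulled down on beads, was sequenced in 14 libraries, and total RNA of WT cells in the other 2. All lines, WT included, had auxin (IAA) for 24 h, which drives the degradation of proteins that carry an auxin-inducible degron (AID). Per the labels, replicates are separate clones or cell lines: WT replicate 2 overexpresses Tir1 and BirA, and WT replicate 1 does not. Labelled spike-in cells were added before purification, Drosophila S2 cells in project 1 and S. pombe cells in projects 2 and 3. Unlabelled S. cerevisiae RNA was also added in project 1, but the tables hold no S. cerevisiae genes, so it was not analysed here.

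The authors deposited raw read counts per mouse Ensembl gene and raw read counts per spike-in gene for each project. The mouse tables list 30278, 27831 and 28585 genes, and those of spike-in genes list 17737, 7259 and 7259. The authors also deposited a normalized signal, which was checked to be the raw count divided by a size factor per library. That factor was 0.891 to 0.914 of the spike-in median-of-ratios factor computed here in project 1, equal to it in project 2, and 0.980 to 0.981 of it in project 3. The deposited tables further hold the authors' log2 fold change and p-value of each mutant against WT, and other annotation such as the median transcript length in bases. The submitters' processing notes list bcl2fastq 2.17.1.14, cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a, HTSeq 0.6.1p1 and DESeq2 1.16.1, and the builds mm10, BDGP6, sacCer3 and ASM294v2. Gene positions are those of the deposited tables (mm10), and 31675 of 32826 genes (96.5%) had the same chromosome, start and end in the GENCODE M21 annotation.

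All values were computed from the raw counts, with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes passed edgeR's filterByExpr with a minimum count of 10. Libraries were scaled by TMM on mouse genes, which sets the bulk of genes to no change, and tested with edgeR's quasi-likelihood test (robust) with Benjamini-Hochberg adjustment at 0.05. Unless another tool is named, each adjusted p of a gene is from that test. Each mutant was compared with the WT libraries of its own project, without a block, because clone numbers have no WT counterpart. AID-Yeats2 was also compared with Supt7l-/- within project 2. The AID-Yeats2 and AID-Zzz3 effects, each against its own WT, were compared in a joint fit of the 14 4sU libraries. WT 4sU RNA was compared with WT total RNA in project 1, and Tir1/BirA overexpression was tested in the 6 WT 4sU libraries with project as a block. The amount of 4sU RNA was measured as the ratio of the effective library size (TMM) of mouse genes to that of spike-in genes with at least 10 counts in each 4sU library of the project.

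For 33 gene lists, members past the threshold were counted over all genes tested and adjusted over the list alone, and lists with at least 5 members tested were compared with all other genes by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. Camera was run again with the correlation estimated from the libraries. That run also rests on the residual degrees of freedom of the fit, 2 or 3 in all but the joint fit. It therefore has little power, and a list not called there is not shown to be unchanged. Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes of a mutant are the targeted gene, the 6 largest rises and the 6 largest falls, the 3 members with the smallest p of each list called by camera, and the 3 naive pluripotency genes with the smallest p. The largest changes were taken among protein-coding genes with a full symbol, adjusted p under 0.05, the same sign under spike-in scaling, a mean of at least 1 CPM (reads scaled to the effective library size), and both clones beyond both WT libraries. The other comparisons name 5 genes per direction.

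Alternatives were spike-in scaling, DESeq2 size factors, no filter or at least 50 counts in every library of either group, DESeq2 in place of edgeR, joint fits, blocks and leaving out each library. In a fit that leaves out a library of a pair, the lone library is assumed to vary like the other groups. Beyond the gene symbols, spans and types of the deposited tables no annotation was used, and no library was excluded.

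Sums of mouse gene counts ranged from 8268061 to 15994518 in 4sU libraries and from 4903998 to 6378707 in total RNA. Spike-in sums ranged from 803588 to 2335495 and from 3137567 to 4464088. Intervals and limits from counts cover counting error only, since reads without molecular identifiers are not independent molecules. Each fit was tested on simulated data, counts for the real genes with 200 genes of at least 1 CPM changed. The simulated genes changed 2-fold were recovered in 68.7% (AID-Tada3), 77.6% (AID-Yeats2), 67.2% (Supt7l-/-) and 64.2% (AID-Zzz3) of cases. At 1.5-fold these shares were 40.3%, 56.7%, 34.3% and 22.4%. With each gene's own dispersion estimate, false calls made up 27.0%, 11.9%, 13.2% and 7.63% of the calls, above the nominal 5%. A second simulation with dispersions on the fitted trend, added after that result, gave 5.44%, 3.29%, 5.96% and 5.07%. It leaves out the variation of dispersion between genes around the trend. These shares therefore do not show that the real fits keep to 5%.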

Results

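Newly synthesized RNA was measured in mouse embryonic stem cells with lesions in SAGA and ATAC, coactivator complexes that acetylate histones at promoters. Tada3 belongs to the acetyltransferase module that both complexes share, Supt7l to the core of SAGA, and Yeats2 and Zzz3 to ATAC. Per the labels, AID-Tada3, AID-Yeats2 and AID-Zzz3 cells carry a degron on the protein, and Supt7l-/- cells are knockouts. Each mutant had 2 clones, compared with 2 WT lines of the same project, and 2 libraries of total RNA served as a reference for WT cells. The 4sU libraries of project 1 held 15852542 and 14780983 mouse gene counts (WT) and 15183636 and 15994518 (AID-Tada3). Those of project 2 held 10542251 and 9488959 (WT), 9713069 and 9790639 (AID-Yeats2), and 8684869 and 9459757 (Supt7l-/-). Those of project 3 held 11830720 and 10882900 (WT) and 8268061 and 13003804 (AID-Zzz3), and the total RNA libraries 4903998 and 6378707. Between replicates of a group, log2 counts of genes had Pearson correlations of 0.969 to 0.993 across genes, which are not independent replicates.

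The targeted genes were still transcribed in every mutant library. Tada3 (ENSMUSG00000048930, mm10 chromosome 6, 113366025 to 113377883) stood at 12.2 and 10.5 CPM in the AID-Tada3 clones and at 31.3 and 23.9 CPM in WT. Its log2 fold change of -1.28 ± 0.17 (SE, n = 2 per group) had an adjusted p of 0.0577 in edgeR. It was called under spike-in scaling (-1.46, adjusted p = 1.37e-06) and in the authors' deposited table (-0.94, adjusted p = 0.00182). Without WT replicate 1 or WT replicate 2 the log2 fold change of Tada3 was -1.076 and -1.455, and without AID-Tada3 replicate 1 or 2 it was -1.385 and -1.17. The fall was called without either WT library and not without either clone. Such a fit takes its spread from the remaining pair alone, so these calls do not show that the fall depends on a single library. Next to it on the chromosome, Arpc4, which encodes a subunit of the actin-nucleating Arp2/3 complex (ENSMUSG00000079426, 113378115 to 113390448), fell by 1.28 ± 0.11 (adjusted p = 0.00962, edgeR). Ttll3, which overlaps the end of Arpc4, had a log2 fold change of -1.08 (adjusted p = 0.178, edgeR). On the other side of Tada3 Camk1, the nearest, had -0.47 (adjusted p = 0.820, edgeR), Ogg1 -0.02, Gm15492 -0.23 and Brpf1 -0.01. These neighbours, except Arpc4, were chosen after their values were seen. Yeats2 (ENSMUSG00000041215, chromosome 16, 20141063 to 20232573) stood at 109 and 188 CPM in the AID-Yeats2 clones and 242 and 256 CPM in WT (log2 fold change -0.74 ± 0.29, adjusted p = 0.284 in edgeR). This fall was called under spike-in scaling (-1.21, adjusted p = 2.77e-05) and in the authors' table (-0.81, adjusted p = 0.0202). Without AID-Yeats2 replicate 2 its value was -1.19 and was called (adjusted p = 1.25e-04), whereas without replicate 1 it was -0.40 (adjusted p = 0.0522). Supt7l (ENSMUSG00000053134, chromosome 5, 31514564 to 31527807) stood at 8.87 and 14.1 CPM in the Supt7l-/- clones and 13.9 and 14.3 CPM in WT (-0.29 ± 0.20, adjusted p = 0.479 in edgeR), with -0.00314 without Supt7l-/- replicate 1 (adjusted p = 0.998) and -0.67 without replicate 2 (adjusted p = 0.241). Counts per gene do not show which part of a targeted gene was transcribed. Zzz3 (ENSMUSG00000039068, chromosome 3, 152395473 to 152462826) stood at 288 and 300 CPM in the AID-Zzz3 clones and 430 and 448 CPM in WT, and fell by 0.58 ± 0.09 (adjusted p = 0.0340, edgeR). Its log2 fold change was -0.557 without AID-Zzz3 replicate 1 and -0.612 without replicate 2, though the call ended in both fits.

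Mouse 4sU RNA was lower relative to spike-in RNA in both clones of AID-Yeats2, Supt7l-/- and AID-Zzz3 than in either WT library of the same project. AID-Yeats2 cells held 4.66 ± 0.572 mouse counts per spike-in count (SD, n = 2) against 6.57 ± 0.0240 in WT, or 70.7% of WT. Supt7l-/- cells held 5.12 ± 0.913, or 77.4%, and AID-Zzz3 cells 10.5 ± 0.0859 against 13.6 ± 0.881, or 77.8%. AID-Tada3 cells held 6.82 ± 0.545 against 7.61 ± 0.728, or 89.6%, with 1 of 2 clones below both WT libraries. The exact permutation p (two-sided) was 0.667 for AID-Tada3 and 0.33 for the others, the smallest that 2 against 2 libraries allow, so this test cannot pass 0.05 in a single comparison. The log2 difference of -0.50 in AID-Yeats2 was -0.63 without its replicate 2, that of -0.37 in Supt7l-/- was -0.18 without its replicate 1 and -0.55 without its replicate 2, and that of -0.36 in AID-Zzz3 was -0.29 without WT replicate 1. AID-Tada3 (-0.16) ranged from -0.26 to -0.06 with a library left out. TMM scaling, used in what follows, reports each gene relative to the other mouse genes. Spike-in scaling moved the median of all genes to -0.16 (AID-Tada3), -0.50 (AID-Yeats2), -0.36 (Supt7l-/-) and -0.36 (AID-Zzz3), and therefore the split of genes into higher and lower.

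**Figure D1:**
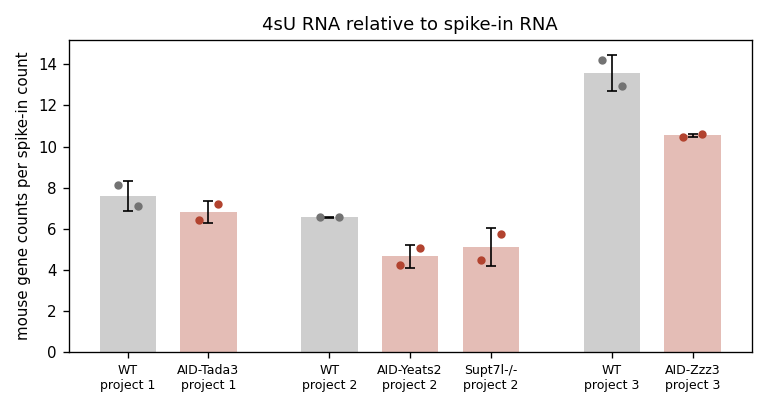
Mouse gene counts per spike-in count (y axis) in each 4sU library, by group and project, with the mean and SD of each group. Both clones of AID-Yeats2, Supt7l-/- and AID-Zzz3 sit below both WT libraries of their project, and 1 of 2 AID-Tada3 clones does.

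AID-Tada3 cells showed few genes whose newly synthesized RNA differed from WT beyond the spread between replicates. The 5 that passed all fell: Pkhd1, which encodes the ciliary protein fibrocystin, Arpc4, the Y-linked translation initiation factor gene Eif2s3y, the ribosomal protein paralogue Rpl39l, and the ETS transcription factor gene Etv1. Pkhd1 went from 36.0 ± 6.94 to 13.3 ± 0.943 CPM (SD, n = 2), a log2 fold change of -1.44 (adjusted p = 0.0246, edgeR), and Eif2s3y from 71.2 ± 8.85 to 30.7 ± 1.56 CPM (-1.22, adjusted p = 0.00962). The fall of Eif2s3y was shared by other Y-linked genes. The median of the 5 more highly expressed Y genes was -0.88, against -0.03 to 0.02 for the autosomes. Summed over 6 Y-linked genes, the clones stood at 61.3% and 44.5% of the WT mean, values chosen after they were seen. Rpl39l changed by -0.90 (adjusted p = 0.0421) and Etv1 by -0.73 (adjusted p = 0.0295). Groups of genes moved by small amounts, with no member called over all genes in edgeR. Among 15 Wnt targets the median was 0.40, 2 rose when adjusted over the list alone, and camera gave an adjusted p of 4.27e-05, or adjusted p = 0.775 with an estimated correlation. Cdx2, an intestinal and trophectoderm regulator, stood at 6.75 against 2.73 CPM, and Tcf7 and Nkd1, a transcription factor and a feedback inhibitor of the pathway, had log2 fold changes of 0.40 and 0.69. The Wnt median was 0.24 under spike-in scaling, with 1 called higher. Wnt targets also differed between the WT lines, with a median of 0.30 for Tir1/BirA overexpression, which may enter this difference. The median of 38 cell cycle genes was -0.18 (-0.33 and 2 lower under spike-in scaling, camera adjusted p = 6.08e-06, and adjusted p = 0.775 with an estimated correlation), with Cdk1 at -0.36, Ttk at -0.33 and Bub1b at -0.28. That of 76 cytosolic ribosomal protein genes was -0.13 (-0.29 under spike-in scaling, camera adjusted p = 8.80e-05, and adjusted p = 0.851 with an estimated correlation), with Rpl9 at -0.35 and Rpl31 at -0.30. The 24 genes of cholesterol synthesis had a median of 0.19 (0.02 under spike-in scaling), with 1 higher adjusted over the list alone, and included Hmgcs1 at 0.38 and Sqle at 0.33. Their camera adjusted p was 0.00523 (adjusted p = 0.775 with an estimated correlation). The 18 formative and primed genes had a median of 0.19 (0.03 under spike-in scaling, camera adjusted p = 0.0111, and adjusted p = 0.775 with an estimated correlation) and 3 were higher adjusted over the list alone, Lefty1 (2.14), Zic2 (0.65) and Cdh2 (0.40) having the smallest p.
Mitochondrially encoded genes had a median of 0.53 (0.40 and 3 higher under spike-in scaling, camera adjusted p = 0.00411, and adjusted p = 0.775 with an estimated correlation), with mt-Co1 at 0.59. The mitochondrial share of counts was 0.869% and 1.03% in the AID-Tada3 clones and 0.496% and 0.810% in WT. The 26 p53 targets had a median of -0.13 (-0.30 under spike-in scaling, camera adjusted p = 0.00890, and adjusted p = 0.775 with an estimated correlation), and none of 28 naive pluripotency genes was called by edgeR, 0 also over the list alone. Genes of the amino acid stress response and neural genes had medians of -0.19 and 0.52 (-0.35 with 1 lower, and 0.38, under spike-in scaling, camera adjusted p = 0.0352 and 0.0466, and adjusted p = 0.775 for both with an estimated correlation).

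Over 15099 genes, edgeR called 0 higher and 5 lower in AID-Tada3 cells, with 1208 at an unadjusted p under 0.05, and DESeq2 called 8 and 24. With spike-in scaling the counts were 26 higher and 224 lower, and the authors' deposited table lists 2 and 16. Without WT replicate 1 there were 74 higher and 86 lower, without WT replicate 2 1040 and 1000, and without either clone 0 and 0. Left-out libraries ended list calls too: without WT replicate 2 those of the cell cycle (adjusted p = 0.0521), ribosomal protein (0.947), cholesterol (0.117) and p53 lists (0.0542). Without WT replicate 1 those of the Wnt (0.103), formative (0.0627), mitochondrial (0.121) and p53 lists (0.198) ended. Without AID-Tada3 replicate 1 the cholesterol (0.0786), formative (0.121) and p53 lists (0.169), and without replicate 2 the ribosomal protein (0.192) and mitochondrial lists (0.0511), were no longer called. The amino acid stress list ended without WT replicate 1 (0.329) and AID-Tada3 replicates 1 (0.102) and 2 (0.0830), and the neural list without any of the 4 libraries (0.0521 to 0.573).

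In AID-Yeats2 cells, newly synthesized RNA of cytosolic ribosomal protein genes fell and that of p53 targets rose, relative to other mouse genes. Of 76 ribosomal protein genes, 41 fell and none rose (55 fell adjusted over the list alone), with a median of -0.58. Under spike-in scaling 69 fell and none rose. Rpl29 went from 10.6 ± 1.40 to 3.17 ± 0.541 CPM (SD, n = 2), Rpl38 from 50.9 ± 4.62 to 21.3 ± 0.109, Rpl9 from 72.0 ± 4.47 to 27.2 ± 5.47 and Rpl31 from 88.3 ± 4.62 to 42.1 ± 0.657, with log2 fold changes of -1.73, -1.26, -1.40 and -1.07. Camera gave the list an adjusted p of 3.29e-27, or adjusted p = 0.756 with an estimated correlation. Of 27 p53 targets, 19 rose and none fell (22 rose adjusted over the list alone), with a median of 0.65. Under spike-in scaling 3 rose and 1 fell, with a median of 0.16. They included Mdm2, which encodes the ligase that degrades p53 (0.79, adjusted p = 1.07e-04, edgeR), Trp53inp1 (0.88), the polo-like kinase gene Plk2 (1.1), the epoxide hydrolase gene Ephx1 (1.19), and the cell death genes Bbc3 (1.09) and Fas, from 0.445 ± 0.327 to 2.30 ± 0.624 CPM (2.31, adjusted p = 0.0165, edgeR). Mdm2 and Bbc3 were chosen after their values were seen. Camera gave the p53 list an adjusted p of 7.42e-15, or adjusted p = 0.458 with an estimated correlation. Among 45 translation factor genes 5 fell (7 fell and 1 rose adjusted over the list alone), Eef1g by 1.49, Eif3d by 1.03, Eef2 by 0.59, Eif2s3x by 0.35 and Eif3b by 0.30, the last 2 chosen after their values were seen. The list's median was -0.10, the camera adjusted p 0.00100, and adjusted p = 0.763 with an estimated correlation. With spike-in scaling 26 members fell and none rose, with a median of -0.61. Among 38 cell cycle genes 6 fell (8 fell and 1 rose adjusted over the list alone), including the S-phase genes E2f8 (-1.28), Ccne2 (-1.13) and Tyms (-0.53). The median was -0.10, the camera adjusted p 0.0321, and adjusted p = 0.775 with an estimated correlation. Spike-in scaling gave 19 cell cycle genes lower and none higher, with a median of -0.59. Ribosome biogenesis genes included 5 that fell and 1 that rose among 52 (camera adjusted p = 0.0283, and adjusted p = 0.763 with an estimated correlation), the same counts as adjusted over the list alone. Spike-in scaling gave 25 lower and none higher, with a median of -0.58. Named here are those called with TMM scaling. Pes1 (-0.43), Fbl (-0.49), Nop56 (-0.35), Nop2 (-0.42) and Gnl3 (-0.40), which act in the assembly of ribosomes, fell, and Utp20 rose by 0.29, a value that flipped to -0.21 under spike-in scaling. Nop2, Gnl3 and Utp20 were chosen after their values were seen. In 3 further lists 1 member each fell: Cyp51 of cholesterol synthesis (-0.47), Hyou1 of the unfolded protein response (-0.45) and the seryl-tRNA synthetase gene Sars (-0.53), with 1 lower, 6 lower and 1 higher, and 1 lower adjusted over the list alone. Camera gave these lists adjusted p of 0.0235, 0.0321 and 0.0430, and adjusted p = 0.663, 0.663 and 0.763 with an estimated correlation. The 13 primitive endoderm markers had a median of 0.27 that flipped to -0.23 under spike-in scaling, none was called by edgeR over all genes or over the list alone, and camera gave an adjusted p of 0.0321 (adjusted p = 0.756 with an estimated correlation).

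Outside these groups, the sarcomere gene Actn2 (ENSMUSG00000052374, chromosome 13, 12269426 to 12340760) fell the most, from 20.5 ± 5.69 to 2.87 ± 0.0342 CPM (log2 fold change -2.82 ± 0.24 SE, adjusted p = 1.73e-05, edgeR). Eif4g3, a scaffold of the translation initiation complex (ENSMUSG00000028760, chromosome 4, 137993022 to 138208508), went from 135 ± 17.4 to 25.9 ± 5.34 CPM (-2.38 ± 0.17, adjusted p = 1.97e-04). Tex45 (-2.11), Pimreg (-1.56) and Ahsg, the fetuin A gene (-1.56), were the next largest falls named. After Fas, the largest rises were Kndc1 (2.16), the endocytosis adaptor gene Pacsin1 (1.99), Wipf3 (1.93), Akr1cl (1.90) and the phospholipase gene Plcd4 (1.90). None of 27 naive pluripotency genes was called by edgeR, 0 also over the list alone, and Klf4, with a log2 fold change of 0.34 that flipped to -0.16 under spike-in scaling, and an adjusted p of 0.0519, came closest.

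Over 14513 genes, edgeR called 569 higher and 482 lower in AID-Yeats2 cells, and 59 higher and 3411 lower with spike-in scaling, of which 537 were called both ways in the same direction. The authors' deposited table, which rests on spike-in factors, lists 35 higher and 4641 lower. Without WT replicate 1 there were 1069 higher and 1060 lower, without WT replicate 2 1021 and 954, without AID-Yeats2 replicate 1 133 and 87, and without replicate 2 225 and 161. These ended the calls of 2, 3, 15 and 14 of the 30 named genes called (adjusted p up to 0.365), and 13 kept theirs in all: Actn2, Eif4g3, Rpl29, Rpl31, Rpl38, Rpl9, Eif3d, Eef1g, Trp53inp1, Plk2, Ephx1, E2f8 and Ccne2. The ribosomal protein and p53 lists stayed called without any library, with 32 to 58 and 12 to 20 members called, the p53 count falling from 19 to 12 without AID-Yeats2 replicate 2. Cell cycle genes lower numbered 13, 7, 2 and 3 in those fits, translation factors lower 15, 5, 3 and 2, and ribosome biogenesis genes lower 13, 5, 0 and 1. Without WT replicate 2 the translation factor (adjusted p = 0.148), cell cycle (0.576), ribosome biogenesis (0.576) and primitive endoderm lists (0.233) were not called. Without AID-Yeats2 replicate 2 the cell cycle (0.0559) and ribosome biogenesis lists (0.0553) were not called either, nor was primitive endoderm without WT replicate 1 (0.0578) or AID-Yeats2 replicate 1 (0.151). The lists of cholesterol synthesis (0.0959) and the unfolded protein response (0.142) were not called without WT replicate 2 either, the latter also not without AID-Yeats2 replicate 1 (0.0564) or 2 (0.0553), and that of tRNA synthetases without any of the 4 libraries (0.0618 to 0.108).

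In AID-Zzz3 cells, too, ribosomal protein genes fell and p53 targets rose relative to other mouse genes. Of 76 cytosolic ribosomal protein genes, 16 fell and none rose (50 fell adjusted over the list alone), with a median of -0.60, and 64 fell under spike-in scaling. Rpl9 went from 56.3 ± 1.87 to 21.2 ± 6.77 CPM (SD, n = 2), Rpl31 from 71.8 ± 4.59 to 34.6 ± 5.04, Rps24 from 184 ± 2.78 to 87.9 ± 13.3 and Rps18 from 74.1 ± 2.05 to 33.1 ± 7.21, and Rpl36 changed by -1.82. Camera gave the list an adjusted p of 9.75e-26, or adjusted p = 0.738 with an estimated correlation. Of 27 p53 targets, 9 rose and none fell (19 rose adjusted over the list alone), with a median of 0.64. Under spike-in scaling 9 rose and 1 fell, with a median of 0.28. The apoptosis gene Bbc3 went from 4.44 ± 0.475 to 12.4 ± 0.297 CPM (1.47), Ephx1 rose by 1.11, Plk2 by 1.00, and, chosen after their values were seen, Trp53inp1 by 0.75 and Mdm2 by 0.71. Camera gave the p53 list an adjusted p of 3.19e-12, or adjusted p = 0.549 with an estimated correlation. Among 45 translation factor genes, Eef1g, a subunit of the elongation factor 1 complex, fell (-1.40), with 3 lower adjusted over the list alone and a median of -0.14 (camera adjusted p = 5.18e-04, and adjusted p = 0.636 with an estimated correlation). Among 38 cell cycle genes the S-phase cyclin gene Ccne2 fell (-0.95), with 6 lower adjusted over the list alone and a median of -0.16 (camera adjusted p = 1.84e-04, and adjusted p = 0.738 with an estimated correlation). With spike-in scaling 29 translation factor genes and 26 cell cycle genes were lower and none higher, with medians of -0.50 and -0.53. Replication-dependent histone genes had a median of 0.22 that flipped to -0.15 under spike-in scaling, with 0 of 49 called by edgeR, also over the list alone (camera adjusted p = 0.00710, and adjusted p = 0.968 with an estimated correlation). Mitochondrially encoded genes had a median of 0.29 that flipped to -0.07 under spike-in scaling, with 0 of 7 called and 6 higher adjusted over the list alone (camera adjusted p = 0.00710, and adjusted p = 0.738 with an estimated correlation). Primitive endoderm genes had a median of 0.41 (0.04 under spike-in scaling) and tRNA synthetase genes one of -0.13, each with camera adjusted p = 0.00716, and adjusted p = 0.738 with an estimated correlation. Ribosome biogenesis, amino acid stress and glycolysis genes had medians of -0.05, -0.21 and -0.16, each with camera adjusted p = 0.0452, and adjusted p = 0.815, 0.738 and 0.738 with an estimated correlation. No member of these 5 lists was called by edgeR over all genes, and adjusted over the list alone 2 amino acid stress genes were higher, 1 lower, and 1 glycolysis gene lower. With spike-in scaling 17 of 22 tRNA synthetase, 28 of 52 ribosome biogenesis, 10 of 22 amino acid stress and 12 of 26 glycolysis genes were lower. No primitive endoderm gene was, and none of the 5 lists had a member higher. The mitochondrial share of counts was 0.889% and 0.852% in the AID-Zzz3 clones and 0.656% and 0.721% in WT.

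Among single genes, the protocadherin gene Cdhr2 (ENSMUSG00000034918, chromosome 13, 54701461 to 54736662) rose from 0.0894 ± 0.00567 to 2.60 ± 0.549 CPM (SD, n = 2, adjusted p = 0.0195, edgeR), with too few counts in WT for a fold. The giant muscle protein gene Neb rose by 2.56, the protease inhibitor gene Serpine2 (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180) from 5.03 ± 0.375 to 23.2 ± 2.70 CPM (2.2, adjusted p = 0.00710), Zfp750 by 2.14, Hs3st4 by 2.08 and Ms4a10 by 1.93. Actn2 went from 18.9 ± 3.85 to 3.25 ± 0.486 CPM (-2.56, adjusted p = 0.00710) and Eif4g3 from 135 ± 6.36 to 24.6 ± 7.30 CPM (-2.44, adjusted p = 0.00710). The phosphatase subunit gene Ppp2r2a changed by -1.20 (adjusted p = 0.0195). None of 27 naive pluripotency genes was called by edgeR, 0 also over the list alone.

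Over 14529 genes, edgeR called 99 higher and 44 lower in AID-Zzz3 cells, and 129 higher and 3584 lower with spike-in scaling, of which 127 were called both ways in the same direction. The authors' deposited table lists 73 and 3082. Without WT replicate 1 there were 138 higher and 74 lower, without WT replicate 2 288 and 176, without AID-Zzz3 replicate 1 12 and 2, and without replicate 2 34 and 31. These ended the calls of 4, 2, 17 and 8 of the 20 named genes called (adjusted p up to 0.306), and Serpine2, Actn2 and Eif4g3 kept theirs in all. The ribosomal protein and p53 lists stayed called without any library, but 0 members of either were called by edgeR without AID-Zzz3 replicate 1, and 0 p53 targets without replicate 2. The other ribosomal protein counts were 11, 24 and 14, and the other p53 counts 11 and 12. Without WT replicate 2 the histone list turned to -0.05 (adjusted p = 0.485), without AID-Zzz3 replicate 2 it was not called (0.337), and the mitochondrial list was not called without WT replicate 1 (0.149) or AID-Zzz3 replicate 2 (0.0566). Calls of the other lists without members called ended without WT replicate 1 (ribosome biogenesis 0.201, glycolysis 0.0801), without WT replicate 2 (primitive endoderm 0.178, tRNA synthetases 0.0549, amino acid stress 0.0584, glycolysis 0.106) and without AID-Zzz3 replicate 2 (primitive endoderm 0.0650, tRNA synthetases 0.0775, ribosome biogenesis 0.337, amino acid stress 0.337, glycolysis 0.186).

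**Figure D2:**
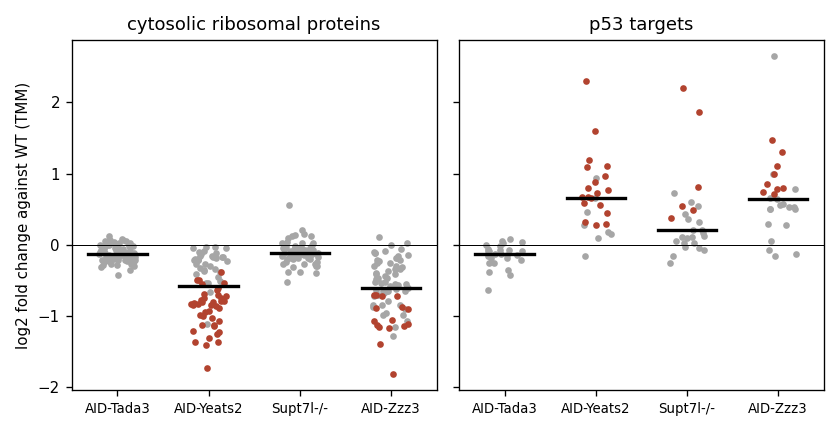
Log2 fold changes against WT (y axis, TMM scaling) of cytosolic ribosomal protein genes and p53 targets in each mutant. Points are genes, red where edgeR's adjusted p is under 0.05, and bars are medians, which for ribosomal proteins are -0.13 (AID-Tada3), -0.58 (AID-Yeats2), -0.12 (Supt7l-/-) and -0.60 (AID-Zzz3). For p53 targets they are -0.13, 0.65, 0.21 and 0.64, and under spike-in scaling the median of p53 targets in Supt7l-/- flips to -0.17.

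AID-Yeats2 and AID-Zzz3 cells, made with different ATAC subunits and sequenced in different projects with their own WT libraries, shared much of their changes. Log2 fold changes correlated across 14116 genes (Pearson r 0.60, Spearman rho 0.558, across genes, which are not independent replicates). Higher in both were 86 genes, against 3.96 that independent lists of those sizes would share, and lower in both were 40, against 1.5, while 0 genes went opposite ways by edgeR. Actn2, Eif4g3, Eef1g, Rpl9 and Rpl31 fell in both, and Plk2, Ephx1, Bbc3 and Trp53inp1 rose in both. A joint fit of the 14 4sU libraries called 0 of 15426 genes as differing between the AID-Yeats2 and AID-Zzz3 effects by edgeR, with 378 at an unadjusted p under 0.05, and DESeq2 called 3 higher and 0 lower in AID-Yeats2. On simulated data this test recovered 46.3% of 2-fold and 75.8% of 4-fold differences, so differences of either size could stay uncalled. Spike-in scaling gave 1 higher and 1 lower, as did the fit without AID-Yeats2 replicate 2. AID-Tada3 effects had across-gene correlations of -0.10 with AID-Yeats2, 0.06 with Supt7l-/- and 0.01 with AID-Zzz3, and Supt7l-/- effects 0.03 with AID-Zzz3. Supt7l-/- and AID-Zzz3 still shared 18 higher and 3 lower genes, against 1.3 and 0.910 for independent lists, with 0 opposite by edgeR.

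**Figure D3:**
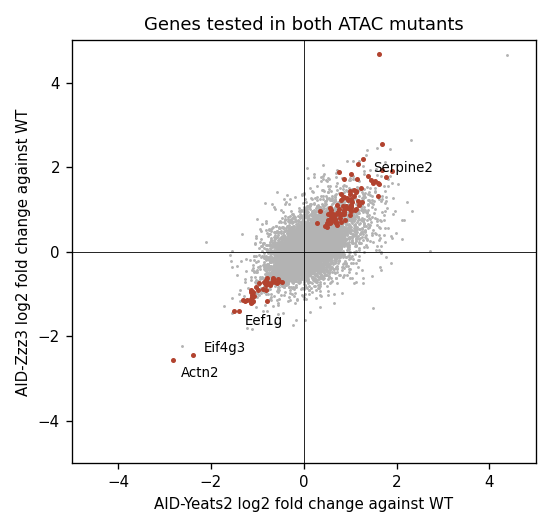
Log2 fold change against WT in AID-Yeats2 (x axis) and AID-Zzz3 (y axis) of genes tested in both. Red points are the genes called in both, 86 higher and 40 lower, and Actn2, Eif4g3 and Eef1g are lower in both while Serpine2 is higher in both.

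Supt7l-/- cells lacked nearly all transcripts of Y-linked genes outside the pseudoautosomal region in both clones. Ddx3y, an RNA helicase gene, stood at 115 ± 27.9 CPM in WT (SD, n = 2) and had no counts in either clone, at least 700.1-fold lower with a floor of 3 counts over both clones. Uba1y also had no counts, at least 15.2-fold lower. The histone demethylase gene Uty went from 520 ± 125 to 0.280 ± 0.247 CPM (1901-fold lower, 95% counting interval 814 to 5854), Eif2s3y from 80.5 ± 21.9 to 0.105 ± 0.149 (736-fold, 204 to 6076) and Zfy1 from 13.3 ± 3.86 to 0.385 ± 0.0984 (34.8-fold, 16.9 to 86.5). Of 9 genes tested on the Y chromosome, 8 were lower, among 293 lower genes in all. These 9 include 2 of the pseudoautosomal region, chosen after their values were seen, Gm47283 (-0.78, adjusted p = 0.0428) and Mid1-ps1, which was not called (-0.56, adjusted p = 0.0955). Among rises, Sp110 (ENSMUSG00000070034, chromosome 1, 85576899 to 85598817), which encodes a nuclear body protein, went from 0.204 ± 0.0145 to 2.2 ± 0.429 CPM (adjusted p = 0.00957, edgeR), with too few counts in WT for a fold. The calcium channel gene Cacna1s rose by 2.45, Kndc1 by 2.11 and Sfta2 by 2.08. Of 27 p53 targets 6 rose (9 adjusted over the list alone, and 2 under spike-in scaling), among them Perp, an apoptosis effector (ENSMUSG00000019851, chromosome 10, 18845020 to 18857073), from 4.05 ± 1.79 to 15.0 ± 2.98 CPM (1.86), Fas (2.2), Plk2 (0.49), Ephx1 (0.55), and, chosen after their values were seen, the antiproliferative gene Btg2 (0.81) and Mdm2 (0.37). The p53 median was 0.21 and flipped to -0.17 under spike-in scaling, and camera gave an adjusted p of 2.78e-04, or adjusted p = 0.814 with an estimated correlation.
Of 38 cell cycle genes 4 fell (13 fell and 1 rose adjusted over the list alone), the DNA methylation cofactor Uhrf1 (-0.50), the replicative helicase subunits Mcm2 (-0.37) and Mcm5 (-0.32), and Top2a (-0.32), of which Mcm2 was chosen after its value was seen. The list's median was -0.21 (camera adjusted p = 2.07e-05, and adjusted p = 0.816 with an estimated correlation). Of 14 Wnt targets, Lef1, a transcription factor of the pathway (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), fell from 17.4 ± 0.559 to 7.05 ± 2.24 CPM (-1.29, adjusted p = 0.00287), and 5 were lower adjusted over the list alone. The list's median was -0.34 (camera adjusted p = 2.80e-05, and adjusted p = 0.814 with an estimated correlation). Wnt targets also differed between the WT lines, with a median of 0.30 for Tir1/BirA overexpression. Of 76 ribosomal protein genes edgeR called 0, also over the list alone, with a median of -0.12 (camera adjusted p = 0.00410, and adjusted p = 0.816 with an estimated correlation). Glycolysis and hypoxia genes had 0 of 25 called, 4 lower adjusted over the list alone, and a median of -0.24 (camera adjusted p = 0.00410, and adjusted p = 0.814 with an estimated correlation). Among 27 naive pluripotency genes, Nr5a2 (-0.26), Tfcp2l1 (-0.24), Il6st (-0.27) and Zfp42 (-0.25) fell and Dppa2 (0.47) rose (Il6st and Zfp42 chosen after their values were seen), with 7 lower and 2 higher adjusted over the list alone and a camera adjusted p of 0.0668. Of 11 ATAC subunits, Wdr5, which histone methyltransferase complexes share, fell by 0.34, with 3 lower adjusted over the list alone (camera adjusted p = 0.0341, and adjusted p = 0.816 with an estimated correlation). The list of nuclear non-coding RNAs had a median of -0.24, with 0 of 23 called and 3 lower adjusted over the list alone (camera adjusted p = 0.0427, and adjusted p = 0.816 with an estimated correlation).

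Over 14513 genes, edgeR called 191 higher and 293 lower in Supt7l-/- cells, and 32 higher and 646 lower with spike-in scaling, of which 283 were called both ways in the same direction. The authors' deposited table lists 4 and 745. Without WT replicate 1 there were 1281 higher and 1348 lower, without WT replicate 2 256 and 405, without Supt7l-/- replicate 1 12 and 28, and without replicate 2 21 and 45. These ended the calls of 0, 5, 17 and 15 of the 22 named genes called (adjusted p up to 0.352), and Ddx3y, Uty, Eif2s3y, Uba1y and Zfy1 kept theirs in all. The p53 list stayed called, with 12, 4, 0 and 1 members higher in those fits, as did the cell cycle list with 18, 3, 0 and 0 lower and the Wnt list with 4, 1, 0 and 1. Without WT replicate 2 the ribosomal protein median turned to 0.00186 (adjusted p = 0.990) and the glycolysis list was not called (0.0722), and without Supt7l-/- replicate 2 neither was called (0.223 and 0.0662). The ATAC and non-coding RNA lists were not called without WT replicate 2 (0.288 and 0.406), Supt7l-/- replicate 1 (0.146 and 0.0672) or 2 (0.0727 and 0.190).

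**Figure D4:**
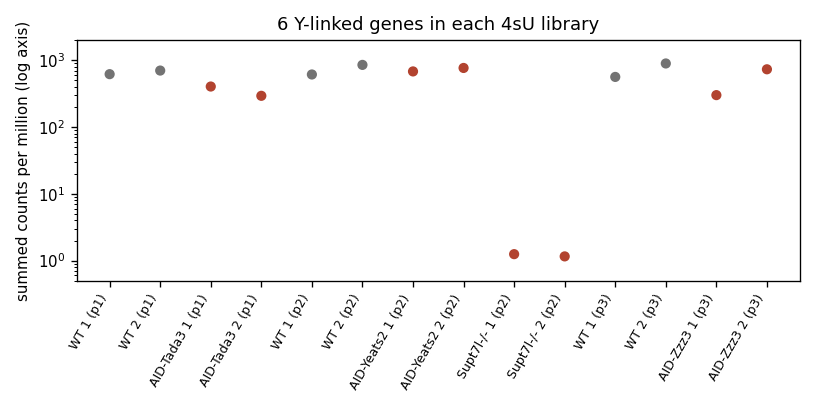
Summed CPM of 6 Y-linked genes outside the pseudoautosomal region (y axis, log scale) in each 4sU library, WT in gray and mutants in red, with the project in brackets. Both Supt7l-/- clones stand at 0.171% and 0.158% of the WT mean of their project.

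AID-Yeats2 and Supt7l-/- cells, compared with each other within project 2, differed in ribosomal protein genes, Y-linked genes and, under TMM scaling, in p53 targets and naive pluripotency genes. Of 76 ribosomal protein genes, 43 were lower in AID-Yeats2 than in Supt7l-/- cells and none higher (48 lower and 1 higher adjusted over the list alone), with a median difference of -0.56 (38 lower and none higher under spike-in scaling, camera adjusted p = 2.58e-14, and adjusted p = 0.750 with an estimated correlation). Of 27 p53 targets, 15 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.44 (1 higher, 1 lower and 0.32 under spike-in scaling, camera adjusted p = 1.38e-05, and adjusted p = 0.60 with an estimated correlation). Naive pluripotency genes were higher for 11 of 27 and lower for 1 (14 and 1 adjusted over the list alone), with a median of 0.20 (none higher, 1 lower and 0.08 under spike-in scaling, camera adjusted p = 0.00466, and adjusted p = 0.60 with an estimated correlation). Wnt targets were higher for 5 of 14, Dkk1, Lef1, Tnfrsf19, Ccnd1 and Apcdd1 (6 adjusted over the list alone), with a median of 0.40 (none called and 0.25 under spike-in scaling, camera adjusted p = 0.00529, and adjusted p = 0.60 with an estimated correlation). Eif4g3 was lower in AID-Yeats2 cells, at 25.9 ± 5.34 against 110 ± 15.9 CPM (SD, n = 2), as was Sh3tc2, a gene for endosome recycling in Schwann cells (-2.42), Tex45 (-2.27), Sfta2 (-2.07) and the bradykinin receptor gene Bdkrb2 (-1.90). The 5 largest rises were the Y-linked Ddx3y, Uty, Eif2s3y, Uba1y and Kdm5d, which were absent or nearly so in Supt7l-/- cells. Perp was the p53 target that was lower (-1.40), and Dppa4 the naive pluripotency gene that was lower (-0.69), and these, like the 5 Wnt targets, were chosen after their values were seen. The log2 fold changes of both mutants against WT correlated with r = 0.18 across genes, and shared 51 higher and 20 lower genes, against 7.49 and 9.73 for independent lists, and 40 went opposite ways. Both used the same WT libraries. In 20 simulated sets with no effects those controls alone gave a correlation of 0.49 ± 0.02 (SD). The covariance was 0.0423, against 0.0360 observed, a difference of -0.00625. These sets shared 0.5 higher (0 to 2) and 0.55 lower genes (0 to 2) on average. With no effects few genes are called at all, so these counts cannot show how many shared calls the common controls add to real effects. In a split added after the data were examined, each mutant had a WT library of its own. The WT lines differ in Tir1/BirA overexpression, and the split puts that difference into both effects with opposite signs. It therefore cannot show the correlation free of the controls. With WT replicate 1 for AID-Yeats2 and WT replicate 2 for Supt7l-/- the correlation was -0.12, with 137 higher and 87 lower in both, against 86.7 and 84.6 for independent lists, and 642 opposite. The other way round it was 0.07, with 100 higher and 61 lower, against 18.2 and 28.4, and 79 opposite. Over 14513 genes edgeR called 1299 higher and 1062 lower, and 332 and 391 with spike-in scaling. Without AID-Yeats2 replicate 1 there were 448 and 231, without its replicate 2 651 and 409, without Supt7l-/- replicate 1 506 and 328, and without its replicate 2 427 and 319, which ended the calls of Sh3tc2, Tex45, Sfta2 and Bdkrb2 each time (adjusted p up to 0.209). With those libraries left out, ribosomal protein genes lower numbered 29, 37, 28 and 36, p53 targets higher 12, 10, 13 and 10, naive pluripotency genes higher 1, 6, 2 and 1, and Wnt targets higher 1, 1, 1 and 3.

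WT 4sU RNA, from transcripts made within 15 min, held far less of histone and respiratory chain mRNA than total RNA. It held more RNA of 6 of the 7 mitochondrially encoded genes tested. The whole mitochondrial share of counts was 0.496% and 0.810% in 4sU RNA and 0.529% and 0.603% in total RNA, so it was not higher in both lines. Replication-dependent histone genes were lower in 4sU than in total RNA for 52 of 53 members, also adjusted over the list alone, with a median of -4.29. Hist1h4h stood at 11.3 ± 1.5 against 675 ± 101 CPM (SD, n = 2), Hist2h2ab at 0.268 ± 0.0773 against 14.8 ± 1.84 and Hist1h2ad at 2.94 ± 0.777 against 135 ± 33.4. Nuclear genes of oxidative phosphorylation were lower for 63 of 74 members and higher for 5, the ATP synthase genes Atp5j, Atp5l, Atp5g2 and Atp5o and the complex I gene Ndufs5 (the same adjusted over the list alone), with a median of -2.25, and mitochondrial ribosomal protein genes lower for 58 of 73 and higher for 6 (59 and 7 adjusted over the list alone). Rpl36al (-5.86) and Scand1 (-5.58) were the largest falls outside histones among the protein-coding genes that the rule admits. Some pseudogenes and small RNA genes fell further, with a median of -7.05 for 3 small non-coding RNA genes. Mitochondrially encoded genes were higher for 6 of 7 and lower for mt-Co1 (-2.60), also adjusted over the list alone, with a median of 2.63 (mt-Co1 and the 5 higher genes of oxidative phosphorylation chosen after their values were seen), and mt-Nd6, the mitochondrial gene on the light strand, stood at 483 ± 128 against 4.91 ± 1.99 CPM. Irf2, an interferon response regulator, stood at 4.42 ± 1.42 against 0.195 ± 0.275 CPM and Ppp1r14c at 1.95 ± 0.344 against 0.0972 ± 0.138, and Asmt and Chst9 had no counts in total RNA, so that no fold is given. Camera gave the histone list an adjusted p of 1.16e-17, the oxidative phosphorylation list 5.69e-12, the mitochondrial ribosomal protein list 9.58e-09 and the mitochondrially encoded list 0.0477. With an estimated correlation these were adjusted p = 0.583, 0.583, 0.583 and 0.601. Over 14494 genes edgeR called 4409 higher and 4776 lower in 4sU RNA, and with cell line as a block, which pairs the 4sU and total libraries of a line (correlation of the pairs 0.42), 5288 and 5397. Left-out libraries moved these between 3612 and 4148 higher and 3962 and 4896 lower. The 5 oxidative phosphorylation genes higher became 3 without total RNA replicate 1, 2 without 4sU WT replicate 1 and 3 without 4sU WT replicate 2, and Chst9 was not tested without 4sU WT replicate 1. Ribosomal RNA was depleted from total but not from 4sU libraries, per the labels, and no scaling between RNA fractions was attempted with spike-ins.

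WT cells that overexpress Tir1 and BirA, the ubiquitin ligase adaptor for degrons and a biotin ligase, differed from WT cells without them in single genes. The imprinted growth regulator gene Grb10 (-1.86, 12.1 ± 2.78 against 43.2 ± 1.27 CPM, SD, n = 3) fell, as did Rhox5 (-2.82), Serpina3m (-2.60) and the leucine-rich repeat genes Pramel6 (-2.31) and Pramel7 (-2.03), which are known in early embryos. The oxidase gene Duox1 (1.15), Galnt18 (1.13), the xenobiotic-metabolizing Cyp1b1 (1.06), Olfr45 (1.03) and the innate immune receptor gene Nod2 (0.89) rose. Of 7 mitochondrially encoded genes mt-Nd6 (0.42) rose (7 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.03e-04, and adjusted p = 0.899 with an estimated correlation). Of 6 aryl hydrocarbon receptor targets Cyp1b1 and Cyp1a1 (0.53) rose (3 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0404, and adjusted p = 0.899 with an estimated correlation). Here mt-Nd6 and Cyp1a1 were chosen after their values were seen. Camera called 7 lists with no member called by edgeR, each at adjusted p = 0.899 with an estimated correlation. Medians were 0.21 for 23 nuclear non-coding RNAs (camera adjusted p = 4.13e-04), 0.30 for 14 Wnt targets (0.00932) and -0.37 for 8 trophectoderm genes (0.0193), with 1 higher, 1 higher and 3 lower adjusted over the list alone. The medians of ribosomal protein genes at 0.10 (camera adjusted p = 1.64e-04), cell cycle genes at 0.09 (0.00302), translation factors at 0.08 (0.00423) and ribosome biogenesis genes at 0.05 (0.0343) flipped to -0.00995, -0.02, -0.02 and -0.06 under spike-in scaling, with 0 called over the list alone. The mitochondrial share was 0.496%, 0.475% and 0.656% in WT replicate 1 and 0.810%, 0.712% and 0.721% in WT replicate 2. Over 14181 genes edgeR called 62 higher and 114 lower with project as a block, and 2 and 10 without it, and spike-in scaling gave 71 and 575 with a median of all genes at -0.11. Without project 1 the fit called 540 and 688, without project 2 0 and 3, which ended 9 of the 10 named calls (adjusted p of 0.0960 to 0.470, Grb10 excepted), and without project 3 36 and 63, which ended those of Duox1 (0.0951), Olfr45 (0.127) and Nod2 (0.124). Mitochondrially encoded genes higher numbered 4, 0 and 7 in those fits, and aryl hydrocarbon receptor targets higher 3, 0 and 1. Since this difference lies between the WT replicates, it is part of the spread against which every mutant was tested. The titles of the mutant libraries do not state Tir1/BirA overexpression. A share of the difference may therefore also enter the mutant effects, and AID-Yeats2 against Supt7l-/-, where the design cannot separate it. Mitochondrially encoded genes, with a median of 0.47 here, had medians of 0.53 in AID-Tada3, 0.13 in AID-Yeats2, -0.24 in Supt7l-/- and 0.29 in AID-Zzz3. Wnt targets, with a median of 0.30 here, had medians of 0.40 in AID-Tada3, -0.11 in AID-Yeats2, -0.34 in Supt7l-/- and 0.04 in AID-Zzz3.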

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

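The tests of differences between mutant effects, except those of AID-Yeats2 with Supt7l-/- and with AID-Zzz3, the restriction of Y-linked genes to those outside the pseudoautosomal region, and the 2 tests of exchanged libraries, Y chromosome loss, independent spike-in error and carry-over of stable RNA were chosen after the result was seen.

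Most pairs of mutants differed in tests of the difference itself, but a joint fit of AID-Yeats2 and AID-Zzz3 effects called 0 of 15426 genes by edgeR, with 378 at an unadjusted p under 0.05 and 3 higher and 0 lower by DESeq2. AID-Yeats2 and Supt7l-/- cells, compared within project 2, differed in 1299 genes higher and 1062 lower in AID-Yeats2, with a median difference of -0.56 for ribosomal protein genes and 0.44 for p53 targets (camera adjusted p = 2.58e-14 and 1.38e-05, and adjusted p = 0.750 and 0.60 with an estimated correlation). In a joint fit of the 14 4sU libraries, the AID-Yeats2 effect exceeded the AID-Tada3 effect in 166 genes and was below it in 55, with medians of -0.44 for ribosomal protein genes and 0.82 for p53 targets (camera adjusted p = 6.82e-17 and 2.66e-18, and adjusted p = 0.855 and 0.0135 with an estimated correlation). The AID-Zzz3 effect exceeded the AID-Tada3 effect in 129 genes and was below it in 32, with medians of -0.49 and 0.77 (camera adjusted p = 2.88e-19 for both, and adjusted p = 0.757 and 0.0121 with an estimated correlation). It exceeded the Supt7l-/- effect in 125 genes and was below it in 67, with medians of -0.48 and 0.47 (camera adjusted p = 1.60e-15 and 1.10e-05, and adjusted p = 0.820 and 0.363 with an estimated correlation). The Supt7l-/- effect exceeded the AID-Tada3 effect in 1 gene and was below it in 2, with 1605 genes at an unadjusted p under 0.05 and 19 and 43 called by DESeq2. Medians of this difference were -0.0108 for ribosomal protein genes and 0.36 for p53 targets (camera adjusted p = 0.960 and 3.60e-07, and adjusted p = 0.993 and 0.205 with an estimated correlation). Except for AID-Yeats2 against Supt7l-/-, these pairs come from different projects, each against its own WT libraries.

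Lower ribosomal protein transcripts in AID-Yeats2 and AID-Zzz3 cells were tested against 2 technical explanations. A bias by gene span, transcript length or expression was argued against by genes matched in these 3, against which the list stood at -0.52 in AID-Yeats2 and -0.54 in AID-Zzz3, with 0 of 10000 draws of matched genes as low. Less carry-over of stable unlabelled RNA would lower other stable mRNAs too, but nuclear oxidative phosphorylation genes, which were far lower in 4sU than in total RNA, had medians of -0.0542 and -0.0424. Whether ATAC acts on ribosomal protein genes or the cells respond indirectly to its loss was not tested, and a single time of 24 h in auxin does not separate the 2. With an estimated correlation camera did not call the list in either mutant, in a run whose few degrees of freedom can by themselves end a call.

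Less 4sU RNA per spike-in count in mutant than in WT libraries was tested as a pattern over the 3 projects. Independent error in single libraries was argued against by shuffles of labels within projects, of which a one-sided share of 0.00370 (2 of 540) gave a mean difference as low. A few genes that take many counts were argued against too, since the mean log2 difference without the 10 top genes was 0.953 of that with them. Lower transcription may remain as an explanation, and so may fewer mouse cells per spike-in cell in the mutant cultures, which nothing here tests.

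Absence of Y-linked transcripts in both Supt7l-/- clones was tested against 4 explanations, and whether it has to do with the lack of Supt7l was not tested. Exchange with the WT libraries was argued against, since the lowest WT library of the other projects stood at 76.9% of the Y-linked CPM of those labelled WT. Exchange with the AID-Yeats2 libraries stays open: Yeats2, at 98.4% of WT or more in the Supt7l-/- libraries, and correlations with AID-Zzz3 effects of 0.03 for Supt7l-/- and 0.60 for AID-Yeats2 go against it, but the call of the fall of Yeats2 in AID-Yeats2 depends on scaling (adjusted p = 0.284 with TMM in edgeR, 2.77e-05 with spike-in scaling and 0.0202 in the authors' table). Reads assigned to X-linked paralogs were argued against, since these changed by -20.8% of the fall of the Y-linked genes, where a shift of reads needs a rise. Loss of the Y chromosome from the cells may be the cause, and the test of it stays undecided because of Usp9y alone. That gene stood at 12.4% and 19.1% of WT in the clones, from 3 and 5 reads against 36 and 19 in WT. These levels lie between the limits of 5% and 20% set for the test, and so few reads cannot decide it. Zfy1, the next highest of the 6 genes, stood at 3.42% and 2.37%. Summed over the 6 genes the clones stood at 0.171% and 0.158% of WT.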

How the results depend on the processing

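DESeq2 size factors for the gene lists and separate WT libraries for AID-Yeats2 and Supt7l-/- were added as alternatives after the data were examined; the others were planned. Of 216 list results of mutants against WT tested under alternatives 118 kept their direction and call, 96 were no longer called and 2 reversed. Under spike-in scaling lists were not tested, and of 36 medians of lists called in mutants against WT 32 kept their direction and 4 reversed. Of 2103 results of named genes, 1625 kept both, 195 became called, 269 were no longer called, and 14, called in neither fit, changed direction under spike-in scaling. Of 236 counts and summary values 120 stayed within the limits set. Where no reason is given, the cause was not tested.

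Spike-in scaling, which by construction moves all genes by the shift of the library ratio, gave 26 higher and 224 lower genes in AID-Tada3, 59 and 3411 in AID-Yeats2, 32 and 646 in Supt7l-/-, 3584 lower in AID-Zzz3, 575 lower for Tir1/BirA, 332 and 391 for AID-Yeats2 against Supt7l-/-, and 1 and 1 for AID-Yeats2 against AID-Zzz3. It reversed the medians of primitive endoderm in AID-Yeats2 (-0.23), p53 targets in Supt7l-/- (-0.17), and histones (-0.15) and mitochondrially encoded genes (-0.0690) in AID-Zzz3, and, outside those 36, of ribosomal protein (-0.00995), cell cycle (-0.02), translation factor (-0.02) and ribosome biogenesis genes (-0.06) for Tir1/BirA. With no filter on low counts there were 168 and 208 in AID-Tada3, 761 lower in AID-Yeats2, 552 and 693 in Supt7l-/-, 436 and 321 in AID-Zzz3, 388 and 472 for Tir1/BirA, and 1 higher for AID-Yeats2 against AID-Zzz3. DESeq2 gave 8 and 24 in AID-Tada3, 329 and 268 in AID-Yeats2, 170 and 91 in AID-Zzz3, 98 higher for Tir1/BirA, 813 and 584 for AID-Yeats2 against Supt7l-/-, and 3 higher for AID-Yeats2 against AID-Zzz3. With spike-in size factors DESeq2 gave 1 and 24 in AID-Tada3, 35 and 4767 in AID-Yeats2, 10 and 689 in Supt7l-/-, and 3241 lower in AID-Zzz3.

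One fit of the 14 4sU libraries gave 11 lower in AID-Tada3, 299 and 268 in AID-Yeats2, 34 and 63 in Supt7l-/-, and 325 and 258 in AID-Zzz3. Only the 4 libraries of both groups gave 324 and 220 in AID-Yeats2 and 93 and 170 in Supt7l-/-. A replicate block by clone number gave 2380 and 2115 for AID-Yeats2 against Supt7l-/-, with a correlation of 0.04 within clone numbers. Without the project block, Tir1/BirA gave 2 and 10. With an estimated correlation 0 lists were called in AID-Tada3, AID-Yeats2, Supt7l-/- and AID-Zzz3. These losses cannot be put down to correlation between members alone, since this run has few degrees of freedom. The p53 list in AID-Zzz3, with an estimated correlation of 0.00916 near the preset 0.01, went from an unadjusted camera p of 2.06e-13 to 0.0177. At an expression of at least 10 CPM the correlation of effects was 0.0545 for AID-Yeats2 with Supt7l-/- and 0.774 for AID-Yeats2 with AID-Zzz3. With separate WT libraries that of AID-Yeats2 with Supt7l-/- reversed to -0.12 (WT replicate 1 for AID-Yeats2) or moved to 0.0727 (WT replicate 2). The difference in Tir1/BirA between these WT libraries enters both values.

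With a library left out, genes higher and lower ranged from 0 to 1040 and 0 to 1000 in AID-Tada3, 133 to 1069 and 87 to 1060 in AID-Yeats2, 12 to 1281 and 28 to 1348 in Supt7l-/-, and 12 to 288 and 2 to 176 in AID-Zzz3. They ranged from 427 to 651 and 231 to 409 for AID-Yeats2 against Supt7l-/-, from 0 to 1 and 0 to 1 for AID-Yeats2 against AID-Zzz3, and from 0 to 540 and 3 to 688 for Tir1/BirA with a project left out. Lists called ranged from 5 to 6 in AID-Tada3, 3 to 8 in AID-Yeats2, 3 to 12 in Supt7l-/- and 5 to 12 in AID-Zzz3. The log2 spike-in ratio ranged from -0.63 to -0.37 in AID-Yeats2, -0.55 to -0.18 in Supt7l-/- and -0.43 to -0.29 in AID-Zzz3. The ribosomal protein median in Supt7l-/- ranged from -0.225 to 0.00186, reversed without WT replicate 2, and that of histones in AID-Zzz3 from -0.0453, also reversed without WT replicate 2, to 0.484. With 8268061 to 15994518 mouse counts per 4sU library and 2 libraries per group, simulated 1.5-fold changes were recovered in 22.4% to 56.7% of cases in the fits of mutants against WT, in 11.9% for 4sU against total RNA and for the AID-Yeats2 and AID-Zzz3 effects, 47.8% for Tir1/BirA and 56.7% for AID-Yeats2 against Supt7l-/-. Other depths were not simulated.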

Other observations

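The values of Y-linked genes in the other projects and the falls outside the Y chromosome were chosen after they were seen, while the splits of the WT libraries were planned.

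WT cells with Tir1 and BirA differed from those without in 176 genes, and the highest of the other 9 splits of the 6 libraries gave 14. That value came from splits that put both libraries of a project in the same group. With project as a block such a project adds no contrast, so these splits are not like the real one. Each other split with 1 library of every project in each group gave 0. Of the 10 splits 1, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.

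Outside the Y chromosome, the 6 largest falls in Supt7l-/- cells were Slfn9 (-2.72), the melatonin synthesis gene Asmt (-2.36), the aromatase gene Cyp19a1 (-2.17), the potassium channel gene Kcnh8 (-2.04), the transporter gene Slc47a1 (-2.01) and Camk2n1 (-2.0). Asmt lies in the pseudoautosomal region and stood at 19.5% and 18.0% of WT in the clones, Gm47283, of the same region, at 57.9% and 58.6%. Y-linked genes outside that region stood at 61.3% and 44.5% of the WT mean in AID-Tada3, at 41.2% and 100.5% in AID-Zzz3 and at 92.9% and 104.7% in AID-Yeats2 libraries.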
